A study of Mus musculus with 5 samples.

How the data were processed

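The series holds 5 single-color (Cy3) hybridizations to an Agilent mouse miRNA array of release 19, 3 of normal and 2 of tumor colorectal tissue. Per the labels' protocols, total RNA was isolated with TRIzol, its quality was judged by NanoDrop absorbance alone, and 31 ng of it was dephosphorylated, denatured and labeled at the 3' end with pCp-Cy3 by T4 RNA ligase. The groups come from the tissue label. The code MR or NC comes from the description label, which does not define MR, and the protocol uses NC for the negative control miRNA. The labels disagree here: the source label puts all 3 normal samples in 1 class, while the design text names a class of normal tissue from injected mice. The second comparison is therefore named by its codes alone.

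Each array's spot intensity values were extracted with Agilent Feature Extraction 10.7.3.1, protocol miRNA_107_Sep09, per the file headers. The processed intensity is background-subtracted with spatial detrending and is not scaled between arrays, per the file headers. Deposited beside it are the mean spot and local background intensity, a total signal per miRNA summed over its probes, and flags of 0 or 1 per spot for signal well above background, saturation, outliers and detection of the miRNA. The authors' deposited value table of the same arrays holds the processed intensity of every spot rounded to 3 significant digits: 100% of its values lay within 0.5% of it. It is on the linear scale, with medians over all its spots of 0.591, 0.687 and 0.438 on the normal arrays and -0.27 and 0.836 on the tumor arrays, with no centring, and it has 1 channel, so no ratio direction is open. Probe positions are those of the files, on build mm9. No genome of that build was used, so exons and introns were not assigned; 88 of 252 tested miRNAs have no position in the files and 29 have several.

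Each array had 52044 spots, of which 49880 were miRNA spots in 3105 probes for 1247 miRNAs, with 10 to 40 spots per probe. Spots well above background made up 15.9%, 17.1% and 14.9% of the miRNA spots on the normal arrays and 12% and 16.8% on the tumor arrays, and 0 spots were saturated. Tumor replicate 2 stood apart in quality, with 5849 population outlier spots against 2160 to 2444 on the other arrays and an SD of 35.6 over its negative control spots against 3.55 to 5.86. All arrays lay on 1 slide and were scanned in 1 session, so slide and scan could not be tested as batches.

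Control spots and spots flagged as non-uniform or population outliers were left out, and the remaining processed intensities were averaged per probe. A probe counted as detected on an array when over 50% of its spots were well above background. Each array was divided by its 75th percentile over the 254 probes detected on all 5 arrays, and rescaled in common. A floor was then set at a scaled signal of 20.1, or 4.33 on the log2 scale, the median over arrays of the 1st percentile of spots well above background. The brightest probe stood for a miRNA. Of the 1247 miRNAs 969 were detected on no array and 153 on all 5, and the 252 detected on at least 2 arrays and tested are those of all statements. Values at the floor have no order. Where a miRNA was detected on no array of a group, its fold is a lower bound, "at least", from the mean log2 level of the bright group against that of the higher of the lowest detected probe and the probe's own signal per dim array.

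Differences were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 252 miRNAs and a threshold of 0.05. The tumor fit used tissue alone, the second fit tissue and code, and the third their interaction. The 21 miRNA lists are the injected miRNAs, the miR-17-92 and miR-183 clusters, miRNAs raised and lowered in colorectal tumors, smooth muscle, fibroblast and mesenchyme, endothelium, leukocytes, erythroid cells, differentiated intestinal epithelium, the miR-200, let-7, miR-29 and miR-30 and miR-34 families, the Dlk1-Dio3, pluripotency and Hox clusters, neural and neuroendocrine cells, liver and pancreas, and hypoxia. They were fixed before the data were examined, as were all alternatives except the ones given as added. The named miRNAs' rule was fixed then too, apart from a change for the MR comparison given below. Of the lists, 13 had at least 3 tested members and were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other miRNAs. Camera's direction and the sign of the list's median or mean differed for 1 list in the tumor comparison, the miR-29 and miR-30 families, and for 5 in the MR comparison: miR-183, colorectal tumor raised, smooth muscle, let-7 and Hox. Counts "adjusted over the list alone" apply the adjustment within a list. The names printed are, per comparison, the 10 largest called differences in each direction with groups that do not overlap, or, where fewer than 10 passed, those with the smallest p up to 5, with all injected miRNAs and up to 4 members per list. In the MR comparison list members are named only for lists that passed, a limit added after no miRNA had passed there. The rule fixed beforehand names members of every list in both comparisons. A few miRNAs outside this rule are named as chosen after their values were seen, and they went through the same alternatives.

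On simulated arrays with the real mean of each miRNA and limma's moderated variances, drawn independently, 60 of 252 miRNAs were changed in 50 simulations per comparison. The tumor fit recovered 81.6% of changes of 1 and 98.9% of changes of 2 on the log2 scale, with 4.01% of calls false, and the MR fit 82.5% and 98.8% with 4.21% false. The simulation does not cover a mouse shared by both MR arrays, values held at the floor or correlation between miRNAs. These shares therefore need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The alternatives changed the scaling, background correction, probe summary, floor, filter, variance model, terms of the model, arrays and list test 1 at a time.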

Results

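MicroRNAs were measured in colorectal tissue of CPC-Apc mice. In these mice a Cre recombinase under a CDX2 promoter deletes 1 floxed copy of Apc, a tumor suppressor gene of the Wnt pathway, and colorectal tumors form. The labels describe mice that received either a formulated mixture of miR-200c, miR-302a to miR-302d and both strands of miR-369, or a negative control miRNA, by tail vein, in 24 injections at 3 per week that began when the mice were 8 weeks old. Tissue was divided into normal and tumor pieces, and 5 single-color arrays were made: 3 of normal tissue and 2 of tumor tissue. A further label reads MR on normal replicate 1 and tumor replicate 1 and NC on the other 3 arrays, and it is used here as a code without a meaning of its own. The labels do not say whether replicates came from separate mice, so p-values measure the spread between these samples. On the normal arrays 243, 260 and 228 of 1247 miRNAs were detected, on tumor replicate 1 185 and on tumor replicate 2 170. The lowest scaled signal detected was higher on the tumor arrays (28.5 and 27.6) than on the normal arrays (15.2 to 18.4). Fewer detected miRNAs therefore need not mean fewer present. The number of arrays limits the precision of every value. The prefix mmu of all miRNA names is left out.

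The first comparison asked which miRNAs differed between tumor and normal colorectal tissue. Both strands of miR-31, a miRNA known to be high in colorectal cancer, stood far above normal tissue on the tumor arrays. miR-31-5p rose by 5.27 ± 0.46 (SE) on the log2 scale, from 4.67 ± 0.59 (SD, n = 3) to 9.95 ± 0.69 (SD, n = 2). It was detected on 1 of 3 normal arrays and set at the floor on the remaining normal arrays, so its normal mean and these errors depend on the floor, and the difference ran from 3.57 to 6.49 over the alternatives. miR-31-3p was not well above background on any normal array and was at least 11.4-fold higher in tumors, counted from the lowest detected signals of the normal arrays, which lie under the floor, with a measured normal mean at the floor of 4.33 and a tumor mean of 7.61 on the log2 scale. The muscle miRNA miR-1a-3p fell 14.7-fold, from 9.12 ± 0.36 to 5.24 ± 0.94, and its log2 difference was -4.54 without tumor replicate 1 and -3.21 without tumor replicate 2, the array that did not detect it. miR-10b-5p, which lies in a Hox gene cluster, fell 11.5-fold, from 8.71 ± 0.23 to 5.19 ± 0.24. In all, 117 of 252 tested miRNAs passed limma with Benjamini-Hochberg adjustment, 61 higher and 56 lower in tumors. With the number in the sample titles as a replicate block 78 passed, and with the number of the source name 41.

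Among the other miRNAs with the largest rises were 4 that were numbered late in the miRNA register, miR-3968 with a log2 difference of 4.01 ± 0.19 (SE), miR-6366 with 3.35 ± 0.24, miR-5097_v19.0 with 2.94 ± 0.28 and miR-5100 with 2.89 ± 0.18. miR-205-5p, known from squamous epithelium, rose by 2.35 ± 0.41, with a limma adjusted p of 0.0749 without tumor replicate 2. miR-18a-5p rose by 2.25 ± 0.24, miR-96-5p by 2.24 ± 0.27 and miR-19a-3p by 2.03 ± 0.15. Of the deepest falls, miR-215-5p, a miRNA of differentiated intestinal epithelium, had a log2 difference of -3.51 ± 0.70, and miR-10a-5p one of -2.57 ± 0.32. For miR-466g, miR-133a-3p, miR-376b-3p and miR-6393 no tumor array was well above background, and these were at least 6.59-fold, 6.41-fold, 4.92-fold and 4.68-fold lower, from normal means of 7.53, 7.49, 7.11 and 7.03 to tumor means at or near the floor, of 4.33, 4.41, 4.33 and 4.33. miR-133b-3p and miR-3470a had log2 differences of -3.19 ± 0.31 and -2.45 ± 0.49. The limma adjusted p of these 20 miRNAs lay between 0.000773 and 0.0141. The rule that chose them required both tumor arrays on 1 side of all 3 normal arrays. miR-215-5p and miR-133b-3p were detected on 1 of 2 tumor arrays, with the other tumor array at the floor. miR-215-5p lost its call without normal replicate 1 (limma adjusted p = 0.0716), normal replicate 3 (0.0538) or tumor replicate 2 (0.0922), and miR-3470a without normal replicate 1 (0.0535) or tumor replicate 2 (0.111). Leaving out 1 array gave log2 differences from -4.47 to -2.55 for miR-215-5p and from -3.04 to -1.86 for miR-3470a.

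**Figure D1:**
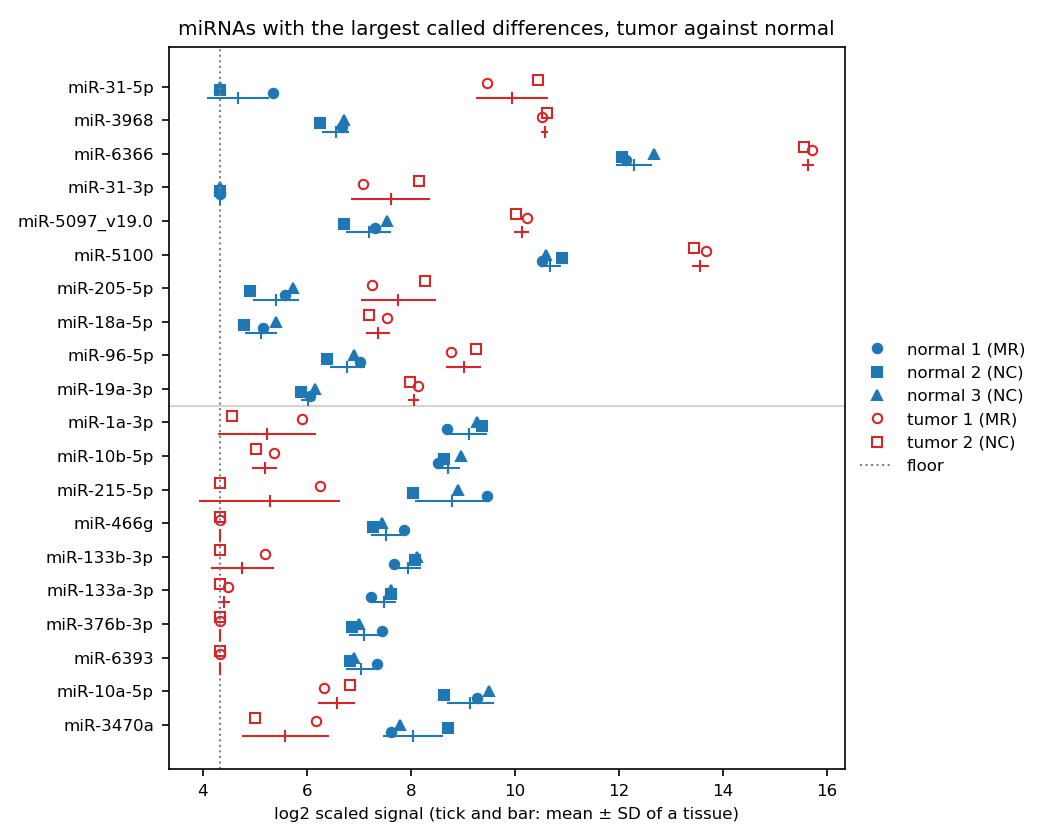
Log2 scaled signal (horizontal axis) on each of the 5 arrays for the 10 miRNAs with the largest rises (top) and the 10 with the deepest falls (bottom) among those that passed limma; filled blue symbols are normal arrays, open red symbols tumor arrays, ticks with bars the mean ± SD of a tissue, and the dotted line the floor. For each of the 20 miRNAs both tumor arrays lie on 1 side of all 3 normal arrays, which the choice of these miRNAs required, and several tumor values lie at the floor of 4.33.

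The miR-17-92 cluster, induced by Myc and known to drive proliferation, was raised together with its paralogous clusters: 10 of 10 tested members rose, and 10 of 10 when adjusted over the list alone, with a median log2 difference of 1.15. Of these 10, 6 passed without scaling, 5 without tumor replicate 1, where miR-20a-5p, named after its values were seen, had an adjusted p of 0.0523 in limma, and 6 without tumor replicate 2. Besides miR-18a-5p and miR-19a-3p, miR-20b-5p rose by 1.32 ± 0.18 (SE) and miR-19b-3p by 1.18 ± 0.17. Those members of the miR-17-92 cluster with 1 position in the files lie on chromosome 14 from 115442951 to 115443427 (mm9, the build of the files' probe positions). All 3 members of the miR-183 cluster (miR-183, miR-96 and miR-182), on chromosome 6 from 30115934 to 30119694, rose, also when adjusted over the list alone. With the number in the sample titles as a replicate block 3 of these 3 passed, and 7 of the 10 above. With the source name's number as a block 0 of the 3 and 6 of the 10 did. miR-182-5p rose by 1.82 ± 0.31 and miR-183-5p by 1.80 ± 0.33, with limma adjusted p of 0.0653 for miR-182-5p without tumor replicate 1 and 0.0922 for both without tumor replicate 2. Of 15 tested members of a list of miRNAs known to be raised in colorectal tumors 13 rose, and 13 when adjusted over the list alone, among them miR-34a-5p, a p53 target, by 1.80 ± 0.22, and 8 of the 15 passed without tumor replicate 1. miR-21a-5p, a miRNA raised in many cancers and named here after its values were seen, rose by 1.62 ± 0.21, from 12.63 to 14.25, but its difference was -0.25 with quantile normalization and -0.19 with normexp. The 2 members that did not pass, likewise named after the values were seen, were miR-322-5p with 0.27, which turned to -0.07 without scaling, and miR-224-5p with -0.09, which passed on the lower side with the total gene signal (-1.26, limma adjusted p = 0.0129) and with a floor at 50% of the value (-0.89, 0.0309). With the blocks above 9 and 6 of the 15 raised members passed. Camera placed the 3 lists above the other miRNAs with adjusted p of 3.62e-05, 0.0369 and 1.67e-05. These lists overlap: miR-183-5p, miR-96-5p, miR-182-5p, miR-18a-5p, miR-20a-5p and miR-92a-3p of the raised list also belong to the miR-183 or miR-17-92 list. With an estimated correlation the adjusted p of each was 0.436, which is past no threshold. The call of the miR-183 list was also lost without normal replicate 1 (camera adjusted p = 0.0532), tumor replicate 1 (0.0515) or tumor replicate 2 (0.099), with quantile normalization and with NC arrays only.

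Muscle miRNAs fell together: 5 of 5 tested members of the smooth muscle list were lower, and 5 of 5 when adjusted over the list alone, with a median log2 difference of -3.08, or -2.68 with undetected members at their bound. miR-143-3p and miR-145a-5p, neighbors on chromosome 18 from 61807494 to 61808909 that mark smooth muscle, belong to it. miR-143-3p, named after its values were seen, fell by 2.41 ± 0.30 (SE) on the log2 scale, and miR-145a-5p was not well above background on either tumor array and was at least 3.41-fold lower, from a normal mean of 6.58 to the floor of 4.33. Of 15 tested members of a list of miRNAs known to be lowered in colorectal tumors 10 fell, and 10 when adjusted over the list alone, and 5 of these 10 are the muscle miRNAs. Without tumor replicate 2, 6 of the 15 passed. miR-10b-5p, miR-215-5p and miR-195a-5p are among the remainder. The median of that list was -2.25, or -1.77 with undetected members at their bound. Camera gave adjusted p of 0.00145 for the muscle list and 3.62e-05 for the lowered list. With an estimated correlation the adjusted p of either list was 0.436.

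In the fibroblast and mesenchyme list miR-214-3p rose by 0.73 ± 0.15 (SE), miR-100-5p fell by 1.11 ± 0.22 and miR-195a-5p by 0.97 ± 0.22, 7 of 10 tested members including miR-125b-5p with 0.41 did not pass, and the median log2 difference was -0.23 (counts adjusted over the list alone were also 1 higher and 2 lower). miR-214-3p did not pass without scaling, with 0.39 (limma adjusted p = 0.324), nor with normexp, with 0.16 (0.622), and miR-125b-5p passed without tumor replicate 1, with 0.58 (0.0468). miR-126a-3p of endothelium had -0.16 ± 0.18. Of 9 tested leukocyte miRNAs miR-223-3p rose by 1.16 ± 0.20, miR-155-5p by 1.06 ± 0.19 and miR-142a-3p by 0.85 ± 0.25, 2 of them when adjusted over the list alone, and miR-342-3p with 0.62 did not pass. The leukocyte median was 0.42 and turned to -0.02 with normexp, and of the 9 members 0 passed without scaling, 1 with normexp and 5 with quantile normalization. The erythroid miRNAs miR-451a and miR-16-5p had -1.18 ± 0.44 and -0.10 ± 0.20, and neither of these 2 tested members passed. miR-451a had -0.50 without tumor replicate 1 and -1.85 without tumor replicate 2, where it passed limma (adjusted p = 0.0445), as it also did with normexp, with a floor at 50% of the value, among miRNAs detected on all 5 arrays and with the code as a term. Of the miRNAs of differentiated intestinal epithelium miR-215-5p was the 1 of 4 tested that fell, also when adjusted over the list alone, with miR-192-5p at -0.92 ± 0.38, miR-194-5p at -0.97 ± 0.44 and miR-192-3p at -0.13 not called, while 3 of the 4 passed on the lower side without scaling and with normexp. Among miRNAs detected on all 5 arrays miR-192-5p and miR-194-5p passed limma (adjusted p = 0.0295 and 0.0317). Leaving out 1 array gave -1.39 to -0.44 for miR-192-5p and -1.41 to -0.53 for miR-194-5p. miR-375-3p and miR-7a-5p, of neuroendocrine cells, had -0.90 ± 0.41 and 0.17 ± 0.23, and neither passed. miR-375-3p did so without scaling, with normexp and among miRNAs detected on all 5 arrays (limma adjusted p = 0.0356), and had -1.41 to -0.40 when 1 array was left out. Camera passed none of the fibroblast (adjusted p = 0.869), leukocyte (0.128) and epithelium (0.255) lists. The leukocyte list did pass on the higher side with quantile normalization (0.0456), and the epithelium list on the lower side with normexp (0.0267). With no filter on detection the leukocyte list passed too (1.84e-05), but there most miRNAs it is compared with are at the floor on every array. It did not pass with those left out. By limma miR-142a-3p lost its call without normal replicate 1 (adjusted p = 0.124), normal replicate 3 (0.111), tumor replicate 1 (0.196) or tumor replicate 2 (0.132), miR-155-5p without tumor replicate 1 (0.0591), miR-100-5p without tumor replicate 1 (0.083) or 2 (0.0629), and miR-195a-5p without normal replicate 2 (0.0571), tumor replicate 1 (0.104) or tumor replicate 2 (0.114).

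Within the miR-200 family, which maintains epithelial identity, miR-141-3p rose by 1.62 ± 0.16 (SE) and was the 1 of 7 tested members that passed, also when adjusted over the list alone. miR-429-3p with 0.40 ± 0.25, miR-200b-5p with 0.47 and miR-200a-3p with 0.30 did not pass, and the family's median of 0.31 turned to -0.03 without scaling. let-7d-5p fell by 0.65 ± 0.17, the 1 of 9 let-7 members that passed, and 0 passed when adjusted over the list alone. let-7a-5p with -0.47, miR-98-5p with 0.51 and let-7g-5p with -0.38 did not pass. The miR-29 and miR-30 families went both ways: miR-30e-5p, miR-30d-5p and, named after its values were seen, miR-30b-5p rose by 0.59, 0.85 and 0.88, miR-30c-5p and miR-30a-5p fell by 0.92 and 0.74, and 3 of 8 tested members did not pass (adjusted over the list alone, 3 higher and 2 lower). Of 6 tested members of the Dlk1-Dio3 cluster, an imprinted miRNA cluster on chromosome 12, 3 passed limma on the lower side, also 3 when adjusted over the list alone, with none of these 3 well above background on a tumor array. miR-376b-3p and miR-376a-3p (at least 1.60-fold, from 5.49 to the floor) were lower. For miR-154-5p no fall is shown, since its normal mean of 4.80 lay below the mean of the lowest signals detected on the tumor arrays. miR-494-3p with -0.50 did not pass. Of 4 tested miRNAs of the Hox clusters miR-10a-5p and miR-10b-5p fell, miR-196b-5p rose by 0.75 ± 0.17 and miR-196a-5p with -0.53 did not pass, as when adjusted over the list alone. The hypoxia miRNA miR-210-3p had -0.01 ± 0.23, not called. Camera passed none of the miR-200 (adjusted p = 0.128), let-7 (0.584), miR-29 and miR-30 (0.978), Dlk1-Dio3 (0.108) and Hox (0.27) lists. The Dlk1-Dio3 list passed on the lower side with the total gene signal (0.0151) and with a floor at 50% of the value (0.0316), with 5 of 6 members lower in each. The Hox list passed on the lower side with normexp (0.0389). The miR-200 list passed on the higher side with no filter on detection (3.77e-06), where most miRNAs it is compared with are at the floor on every array. It did not pass with those left out. Several of these calls changed with scaling or background correction. Lower let-7 members numbered 3 without scaling, 5 with median ratio scaling and 4 with normexp, and for the miR-29 and miR-30 families each of these 3 settings gave 0 higher and 4 lower, and quantile normalization 1 higher and 3 lower. miR-196b-5p lost its call under the same 3 settings, miR-196a-5p passed on the lower side without scaling and with normexp, and miR-376a-3p lost its call with quantile normalization and with a floor of 2 times the value. Calls that limma lost when 1 array was left out were many here. Without tumor replicate 2 the adjusted p was 0.124 for let-7d-5p, 0.0798 for miR-30a-5p, 0.0586 for miR-30c-5p, 0.12 for miR-30d-5p, 0.089 for miR-30e-5p, 0.199 for miR-30b-5p, 0.182 for miR-376a-3p, and 0.0922 for miR-154-5p and miR-196b-5p. Without tumor replicate 1 it was 0.0591 for let-7d-5p, 0.083 for miR-30e-5p, 0.158 for miR-376a-3p, 0.0746 for miR-154-5p and 0.0828 for miR-196b-5p. Without normal replicate 1 it was 0.065 for let-7d-5p, 0.0789 for miR-30d-5p, 0.066 for miR-30e-5p, 0.089 for miR-30b-5p, 0.114 for miR-376a-3p and 0.0551 for miR-196b-5p, without normal replicate 2 it was 0.0855 for miR-30d-5p, 0.119 for miR-30b-5p and 0.0527 for miR-154-5p, and without normal replicate 3 it was 0.0641 for let-7d-5p, 0.0884 for miR-30d-5p and miR-154-5p, 0.0678 for miR-30e-5p, 0.118 for miR-30b-5p and 0.0917 for miR-376a-3p. Leaving out 1 array moved the log2 difference to values from 0.53 to 1.23 for miR-30b-5p and from 0.56 to 1.14 for miR-30d-5p. No member of the pluripotency and of the liver and pancreas lists reached the 2 arrays needed for testing.

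**Figure D2:**
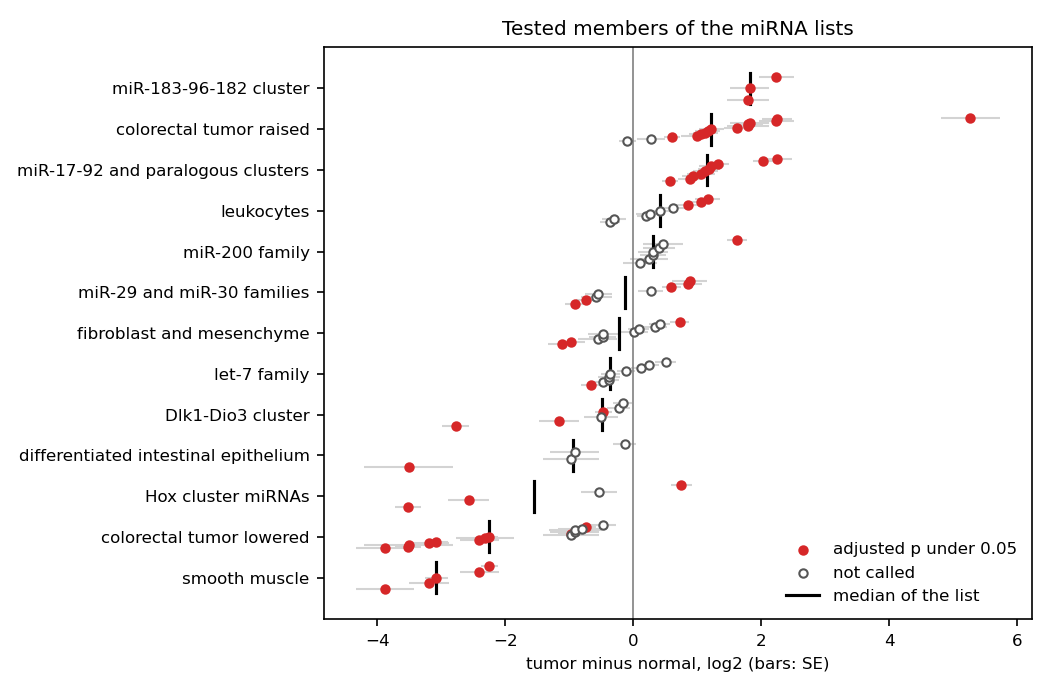
Tumor minus normal log2 difference (horizontal axis, bars SE) of every tested member of the 13 lists with at least 3 tested members; red points passed limma at an adjusted p under 0.05, open points did not, and black lines are list medians. Medians run from -3.08 for smooth muscle to 1.82 for the miR-183 cluster, and the leukocyte and miR-200 medians, at 0.42 and 0.31, fall to -0.02 with normexp and to -0.03 without scaling.

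The 117 calls compare with 138 miRNAs at an unadjusted p under 0.05, and the 5 arrays parted completely by tissue for 71.9% of the 153 miRNAs detected on all 5. For a single miRNA chance gives 20%. The 153 come from the same 5 arrays and may vary together, so their share is not a test against that value. The median log2 difference over all 252 was -0.16. It moved to -0.05 with quantile normalization, -0.38 without scaling and -0.43 with the scanner's total gene signal, and the split of higher against lower calls moved from 61 and 56 to 27 and 55 without scaling, 27 and 72 with normexp and 50 and 87 with the total gene signal. Without tumor replicate 1 limma called 74 miRNAs, without tumor replicate 2, which had the most outlier spots (5849), it called 54, and with the 3 NC arrays alone 0, where 90 had an unadjusted p under 0.05. Of the calls, 27 rest on miRNAs not well above background on either tumor array, whose values there are at or near the floor, and 7 on miRNAs not well above background on any normal array. An exact rank test of 3 against 2 arrays cannot give a two-sided p below 0.2.

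The miRNAs of the injected mixture were read next, although the labels do not say which of these mice received it. miR-200c-3p, an epithelial miRNA, was well above background on all 5 arrays, with unscaled signals of 1599 and 1164 on the MR arrays of normal and tumor tissue and 1409, 1707 and 1845 on the NC arrays. Its log2 difference was 0.04 ± 0.34 (SE) for MR minus NC and 0.25 ± 0.30 for tumor minus normal, and neither passed limma (adjusted p = 0.978 and 0.527). Without scaling both turned negative, to -0.26 and -0.10. Both MR arrays may come from 1 mouse, and if they do, the p of MR minus NC is too small for animals. The other 6 injected miRNAs were not detected on any array by the rule used here. miR-302c-3p, a miRNA of pluripotent stem cells, gave signals of 15.2 and 11.7 on the MR arrays against 4.93, 4.78 and 1.41 on the NC arrays. miR-302a-3p gave 12.8 and 9.17 against 6.01, 5.21 and 2.57, and miR-369-5p gave 14.7 and 9.29 against 7.71, 3.95 and 1.97. For miR-302b-3p, miR-302d-3p and miR-369-3p signals ranged from 1.85 to 5.12 with no such order. These 6 miRNAs lie below the detection rule and were not tested one by one.

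**Figure D3:**
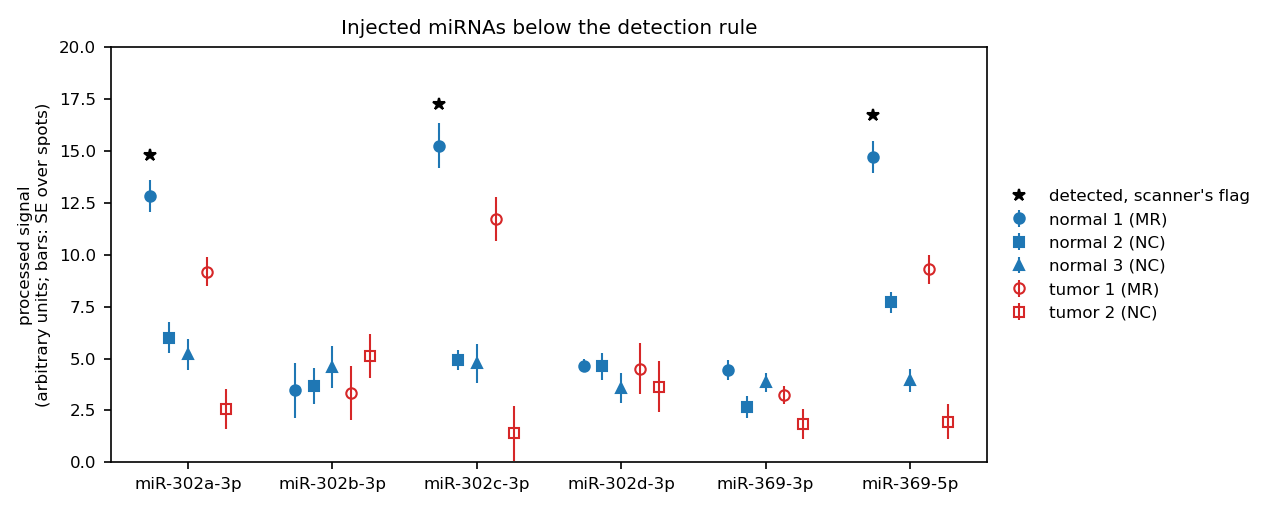
Processed signal (vertical axis, arbitrary units, bars SE over the spots of a probe) of the 6 injected miRNAs that no array detected by the rule used here; blue symbols are normal arrays, red symbols tumor arrays, and stars mark the scanner's own detection flag. miR-302a-3p, miR-302c-3p and miR-369-5p are brighter on both MR arrays, between 9.17 and 15.2, than on any NC array, where the highest is 7.71.

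The remaining comparison set the MR arrays against the NC arrays with tissue as a term. Both MR arrays carry the number 8 in their titles and may come from 1 mouse, which the labels do not settle. If they do, the p-values of every MR against NC test are too small for a comparison of animals. limma called 0 of 252 miRNAs, 6 had an unadjusted p under 0.05, and the smallest adjusted p was 0.973. Values with the smallest p were, for MR minus NC on the log2 scale, miR-215-5p at 1.39 ± 0.39 (SE), miR-5109_v19.0 at 0.53 ± 0.16, miR-652-5p at 0.52 ± 0.17, miR-194-5p at 0.82 ± 0.29 and miR-6360 at 0.80 ± 0.30, and on the lower side miR-451a at -0.88 ± 0.25, miR-100-5p at -0.42 ± 0.15, miR-342-3p at -0.40 ± 0.18, miR-99a-5p at -0.36 ± 0.17 and miR-497a-5p at -0.35 ± 0.17. None of these 10 passed, and miR-652-5p stood at the floor on normal replicates 2 and 3. The interaction of code and tissue, with 1 residual degree of freedom, also gave 0 calls by limma, with 15 miRNAs at an unadjusted p under 0.05 and a smallest adjusted p of 0.672.

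Camera set 3 lists apart between MR and NC, although no member of any list passed, also when adjusted over the list alone. The 4 tested miRNAs of differentiated intestinal epithelium, miR-215-5p, miR-194-5p, miR-192-5p with 0.59 ± 0.32 (SE) and miR-192-3p with 0.23 ± 0.18, lay above the other miRNAs, with a median log2 difference of 0.71 and a camera adjusted p of 0.00644. miR-192-3p stood at the floor on all arrays but normal replicate 1, and miR-215-5p on tumor replicate 2, so their values depend on the floor. The 10 fibroblast and mesenchyme miRNAs, among them miR-195a-5p with -0.31 ± 0.20, lay below them with a median of -0.08 (camera adjusted p = 0.0333), and so did the 9 leukocyte miRNAs, with miR-511-3p, at the floor on both tumor arrays, at -0.23, miR-181a-5p at -0.15, miR-146a-5p at -0.13 and a median of -0.08 (camera adjusted p = 0.0468). With an estimated correlation the adjusted p of each was 0.819, and fry called 0 lists. Each call was lost when any of several arrays was left out. Without normal replicate 2 the camera adjusted p was 0.077 for epithelium, 0.0801 for fibroblasts and 0.143 for leukocytes, and without normal replicate 3 it was 0.0828 for fibroblasts and for leukocytes. All 3 calls were lost without normal replicate 1, which leaves 1 MR array. The epithelium and leukocyte calls were lost without tumor replicate 1 or 2. With tissue as a term, both of these are the same fit as normal tissue only, with 1 MR array. If both MR arrays are of 1 mouse, these p-values too are too small for animals. The epithelium call was also lost with a floor of 2 times the value (0.143), with no filter on detection (0.257) and without the tissue term (0.148). The fibroblast call was lost under 9 of the alternatives other than leaving out 1 array and the leukocyte call under 13, both among them with quantile normalization (0.0569 and 0.0632), normexp (0.0738 and 0.695) and the total gene signal (0.0581 for each). The remaining 10 tested lists did not pass, with adjusted p from 0.393 to 0.93, although let-7 passed on the lower side with normexp (0.0391). Smooth muscle and the lowered list lay on the lower side in normal tissue only and without tumor replicate 1 or 2, and on the higher side without normal replicate 1. The former settings are 1 and the same fit, with 1 MR array, since tissue is a term. Leaving out normal replicate 1 also leaves 1 MR array, so no test is read from these. With no filter on detection camera called 11 lists, but there most miRNAs compared are at the floor on every array.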

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

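The tests of signal in the dim injected miRNAs were written before they were run, but for a pattern already seen in the signals. The plan fixed before the data were examined gave these miRNAs no test of their own. For 3 of the injected miRNAs the scanner's own detection flag, which the comparisons do not use, was set on normal replicate 1, an MR array, and on no NC array. It was not set for them on tumor replicate 1, also an MR array, and 0 miRNAs had it on both MR arrays and on no NC array. On normal replicate 1 and no NC array it was set for 5 miRNAs, the other 2 being miR-340-3p and miR-669o-5p, named after their values were seen and not injected. The signals there were 12.82 for miR-302a-3p, 15.25 for miR-302c-3p and 14.72 for miR-369-5p. The highest of the 3 miRNAs' signals on an NC array was 7.71.

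The pattern weighed is that dim injected miRNAs were brighter on the MR arrays. Of 969 never detected miRNAs, the 3 with the largest MR minus NC difference in signal were these 3. A higher background shared by all probes of the MR arrays is argued against as the whole cause. The median MR minus NC difference in signal of all 969 never detected miRNAs was -0.16. Among them the 6 dim injected miRNAs had a median percentile of 95.1 (one-sided permutation p = 2e-04). That p treats the 6 as independent and restates a pattern already seen, so no weight is put on it. A background of single probes was not tested and stays open. Injected miRNA left in the tissue may account for the pattern if MR marks injected mice, which the labels do not say, and it stays open. Of 10000 random sets of 6, 99.99% had a lower median percentile. That is the same draw as the permutation p above and the pattern itself, so it does not favor this explanation over others. miR-302b-3p stood at 23.3, and RNA in blood or carried onto the tissue was not separated from RNA inside cells. Higher endogenous transcription of the source clusters stays open, since their 23 dim members that were not injected had a median percentile of 60.78 with an SD of 24.3, or 77.1 on scaled signal, and both MR arrays may be of 1 mouse. All but miR-367-3p, of the miR-302 cluster and at 93.7, are of the Dlk1-Dio3 cluster. For none of miR-302a-5p to miR-302d-5p, the opposite strands, were both MR arrays above all NC arrays.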

How the results depend on the processing

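Keeping outlier spots, and dropping the detection filter while leaving out miRNAs at the floor on every array, were chosen after the data had been seen. The signs of the 117 called miRNAs held under the alternatives that tested them, except for 115 of 117 with quantile normalization, 114 with normexp and 115 with a floor of 2 times the value. All 117 have both tumor arrays on 1 side of the normal arrays, so leaving out arrays could not turn a sign. Nor could a change of the filter or variance model alone, so signs that held there test nothing. The counts that follow include such settings. Over all alternatives, values of named miRNAs for tumor against normal kept sign and side of the threshold in 1527 of 1858 cases, lost the call in 271, gained it in 36 and turned in 24. The corresponding list tests gave 312, 10, 11 and 15 of 348. For MR against NC 1 named value gained a call and 7 turned while 355 kept both, and of the list tests 40 lost a call, 10 gained one and 55 turned. Where no cause is named, the cause was not tested. Signal over background limits all of these, since miRNAs near the floor have no order. All arrays were on 1 slide, so no slide block was possible.

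Counts of called miRNAs for tumor against normal moved as follows. Higher calls were 27 without scaling and 27 with normexp. Lower calls were 87 with the total gene signal, 32 with a floor of 2 times the value, and 28 among miRNAs detected on all 5 arrays, where fewer are tested. With no filter on detection limma made 11 calls, 8 higher and 3 lower, and 1013 calls for the interaction of code and tissue, because miRNAs held at the floor on every array have variances near 0. Without these the calls were 119 for tumor against normal, and for the interaction 0, with 42 at an unadjusted p under 0.05. With NC arrays only it made 0 calls, 0 higher and 0 lower, from 3 arrays, with 90 at an unadjusted p under 0.05. Leaving out 1 array gave 54 to 105 calls, 35 to 57 higher and 19 to 48 lower, where a lone sample is assumed to vary like the other group. MR against NC had 1 call with normexp, miR-215-5p at 0.95 (limma adjusted p = 0.044).

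With the title number as a replicate block limma made 78 calls, 36 higher and 42 lower, and miR-200c-3p had -0.014 for tumor minus normal. With the source name's number as a replicate block limma made 41 calls, 22 higher and 19 lower, miR-210-3p had 0.11 and the miR-29 and miR-30 list an adjusted p of 0.980. Normal replicate 3 and tumor replicate 2 share the title number 10, as both MR arrays share 8. The pairing by title number had correlations of deviations of -0.12 and -0.075. With 2 tumor arrays their deviations are mirror images, so such correlations cannot exclude a pairing by either number. The labels do not say that a number names a mouse, so the main fit does not pair the arrays. Of the named calls 14 were lost with the title number and 28 with the source number, and 14 with both: let-7d-5p, miR-25-3p, miR-30a-5p, miR-30b-5p, miR-30d-5p, miR-30e-5p, miR-106b-5p, miR-154-5p, miR-155-5p, miR-195a-5p, miR-196b-5p, miR-214-3p, miR-223-3p and miR-3096b-3p_v19.0.

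Camera with an estimated correlation called 0 lists for tumor against normal and 0 for MR against NC, and fry 8 and 0, of which the leukocyte, Dlk1-Dio3 and Hox lists were not called by camera. With the source number as a replicate block camera also called the miR-200 list (adjusted p = 0.0442). For MR against NC, where both MR arrays may be of 1 mouse, camera called 1 list with quantile normalization, 1 with the total gene signal, 1 with a floor of 2 times the value, 0 among miRNAs detected on all 5 arrays, 11 with no filter, 1 with no filter and floor miRNAs left out, 0 without the tissue term, 1 with outlier spots kept and 0 to 3 when 1 array was left out.

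Differences between tumor and normal that turned were these. miR-210-3p had 0.029 with the 75th percentile over all probes, 0.035 with quantile normalization, 0.025 with the mean of all probes and 0.084 with outlier spots kept. miR-21a-5p had -0.25 with quantile normalization and -0.19 with normexp. Without scaling miR-200c-3p had -0.096, miR-200a-3p -0.037, miR-7a-5p -0.17 and miR-322-5p -0.070. With normexp miR-200b-5p had -0.042, miR-98-5p -0.024, miR-7a-5p -0.16 and miR-322-5p -0.14. miR-7a-5p had -0.068 with NC arrays only, and miR-192-3p 0.17 with outlier spots kept. Leaving out 1 array gave -0.014 to 0.43 for miR-200c-3p, -0.36 to 0.047 for miR-126a-3p, -0.30 to 0.092 for miR-16-5p, -0.070 to 0.41 for miR-7a-5p and -0.23 to 0.22 for miR-210-3p.

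MR minus NC turned for the injected miR-200c-3p, to -0.085 with the 75th percentile over all probes, -0.14 with quantile normalization, -0.26 without scaling, -0.052 with median ratio scaling, -0.10 with normexp and -0.018 with the total gene signal, and it ran from -0.21 to 0.23 when 1 array was left out. With normexp miR-146a-5p had 0.13, miR-181a-5p 0.13 and miR-511-3p 0.042. miR-146a-5p had 0.10 in normal tissue only and -0.43 to 0.10 when 1 array was left out, and miR-192-3p had -0.045 with outlier spots kept.

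List directions for tumor against normal turned for the miR-29 and miR-30 families, with adjusted p of 0.963 (75th percentile over all probes), 0.529 (quantile normalization), 0.685 (no scaling), 0.873 (median ratio), 0.969 (mean of all probes), 0.816 (floor of 2 times the value), 0.495 (detected on all 5 arrays), 0.899 (no filter, floor miRNAs left out), 0.138 (fry), 0.881 (outlier spots kept) and 0.941 to 0.998 when 1 array was left out. They turned for the fibroblast list with 0.938 (total gene signal), 0.566 (no filter) and 0.603 to 0.955 when 1 array was left out.

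List directions for MR against NC turned for these adjusted p. The miR-29 and miR-30 families had 0.837 (75th percentile over all probes), 0.735 (quantile normalization), 0.579 (no scaling), 0.817 (median ratio), 0.695 (normexp), 0.782 (total gene signal), 0.776 (floor at 50% of the value), 0.950 (detected on all 5 arrays) and 0.0103 (no filter). The miR-183 cluster had 0.943 (quantile normalization), 0.419 (normal tissue only), 0.604 (no tissue term) and 0.988 (fry). Smooth muscle had 0.789 (quantile normalization), 0.959 (no scaling), 0.895 (normexp), 0.619 (total gene signal), 0.559 (floor at 50% of the value) and 0.988 (fry). The miR-17-92 clusters had 0.195 (no scaling), 0.695 (normexp), 0.995 (total gene signal) and 0.0224 (no filter). The miR-200 family had 0.846 (normexp) and 0.0353 (no filter), the Hox list 0.803 (normexp) and 0.988 (fry), and let-7 0.702 (mean of all probes), 0.984 (floor of 2 times the value), 0.988 (fry) and 0.863 (outlier spots kept). The lowered list had 0.752 (floor of 2 times the value), 0.000196 (no filter), 0.0270 (normal tissue only) and 0.366 (no tissue term), and the raised list 0.510 (no tissue term) and 0.988 (fry). When 1 array was left out the adjusted p ran from 0.113 to 0.954 for miR-17-92, 0.0801 to 0.937 for miR-183, 0.0801 to 0.989 for the raised list, 0.0118 to 0.454 for the lowered list, 0.0106 to 0.937 for smooth muscle, 0.0828 to 0.958 for miR-200, 0.236 to 0.786 for let-7, 0.626 to 0.954 for miR-29 and miR-30, 0.118 to 0.954 for Dlk1-Dio3 and 0.143 to 0.958 for Hox.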

Other observations

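The tests of neighboring miRNAs, of non-epithelial cells, of the share of muscle and of ends in CCA were chosen after the values had been seen. Among tested miRNAs with 1 position in mm9, 16 groups lay within 10000 bases of each other, and in 8 of them at least 2 hairpins passed limma. In 8 of these 8 all called members went 1 way (one-sided permutation p = 0.00224 over 100000 permutations). In 6 of the 16 groups 1 hairpin passed, as with miR-141-3p at 1.62 beside miR-200c-3p at 0.25, and in 2 groups none did, so the count says nothing of neighbors that were not called. Besides the clusters of the lists, miR-212-3p and miR-132-3p on chromosome 11 from 74986954 to 74987246 rose, miR-132-3p by 0.92 on the log2 scale, and so did miR-181d-5p and miR-181c-5p on chromosome 8 from 86702628 to 86702809, miR-181c-5p by 1.29. miR-212-3p and miR-181d-5p were not well above background on any normal array and were at least 3.65-fold and 4.46-fold higher, counted, as for miR-31-3p, from the lowest detected signals of the normal arrays, which lie under the floor. miR-132-3p and miR-181c-5p lost their calls without scaling and with normexp, miR-181d-5p with normexp, and miR-212-3p with a floor of 2 times the value. With that floor miR-181c-5p lost its call too and had 0.32, so its 1.29 depends on the floor. miR-25-3p, miR-93-5p and miR-106b-5p on chromosome 5 from 138606605 to 138606996 rose by 0.89, 1.06 and 0.93, and these 3 lost their calls without tumor replicate 1 (limma adjusted p = 0.0758, 0.0828 and 0.0686) or tumor replicate 2 (0.112, 0.105 and 0.0749), and without scaling.

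A small number of miRNAs took most of the signal in tumors. miR-6366, miR-3963, miR-21a-5p and miR-5100, picked after their values were seen, held 16.2%, 17.8% and 16.6% of the summed signal of all miRNAs on the normal arrays and 52.9% and 51.3% on the tumor arrays.

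The muscle miRNAs miR-143-3p, miR-145a-5p, miR-133a-3p, miR-133b-3p and miR-1a-3p were lower on the tumor arrays. Scaling between arrays as the cause is argued against, as their median difference was at the weakest -1.79 on the log2 scale over 6 ways of scaling or background correction. A fall of all non-epithelial cells as deep as that of the muscle miRNAs is argued against too, as the fibroblast and mesenchyme miRNAs had a median of -0.225 with an SD of 0.610. Without scaling it was -0.567, against -3.18 for muscle, and there the test's own limit would leave the question undecided. With normexp it was -0.342 against -1.79. Whether these miRNAs stand for all non-epithelial cells was not tested, so this holds only for cells that they mark. A smaller change in their share stays open, since these miRNAs went both ways, as with miR-100-5p at -1.11 and miR-214-3p at 0.73. A smaller share of muscle in the tumor pieces may account for the pattern and stays open: 5 of 5 were lower by at least 2-fold, which is the pattern itself, and whether they fell by 1 common factor could not be read, since 1 of the 5 was detected on all 5 arrays. Lower expression within tumor cells, which the tissue groups allow, was not tested.

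Of the 10 miRNAs with the largest rises in tumors 4 are numbered above 3000: miR-3968, miR-6366, miR-5097_v19.0 and miR-5100. GC content of the probes is argued against, as their median difference was 3.15 before and 3.101 after a fit on GC, and so is scaling, with a lowest median of 2.223 over 6 ways of scaling or background correction. Late numbering alone does not go with a rise, since of 39 such tested miRNAs 7 were called higher and 10 lower. Of the 4, 3 end in CCA, as mature tRNAs do, so fragments of other RNAs on these probes may play a part. That stays open: the other tested miRNAs ending in CCA lay 1.449 above the rest (two-sided permutation p = 0.0418). These are only 3, fewer than the test required, so it decides nothing. They are miR-212-3p, which rose with its neighbor miR-132-3p, the leukocyte miRNA miR-223-3p, and miR-3096b-3p_v19.0. The last lost its call in limma without normal replicate 1 (adjusted p = 0.122), normal replicate 2 (0.0911) or normal replicate 3 (0.0587). Its call was also lost under quantile normalization, no scaling, median ratio scaling and normexp. Its log2 difference was 0.63 without tumor replicate 1 and 1.24 without tumor replicate 2.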
